A study of Drosophila melanogaster with 3 samples.

How the data were processed

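The series holds anti-GFP chromatin immunoprecipitation from whole Drosophila embryos that carry a tagged tgo insertion, with sonicated fragments of 200 to 800 bp, as 3 biological replicates of 1 group per the labels. For each replicate the authors deposited 2 peak lists on dm6, a thresholded list and a longer ranked list, both derived from that replicate's filtered alignments and a control, per the deposited readme. The control itself, the read counts and the alignments were not used here, and the aligner and the peak caller are not given in the sources used here. The names of the lists refer to IDR, the irreproducible discovery rate, which scores how well peaks recur between paired rankings. Which rankings were paired within a single replicate's list is not given in the sources used here. The deposited signal value of each peak is the authors' enrichment measure in unstated units, and it was used only to rank peaks within a list. The deposited score in the thresholded lists ran from 830 to 1000, and it equalled the scaled IDR of the ranked list within 1 unit for all 3605, 4758 and 3026 distinct intervals of replicates 1, 2 and 3 on the major arms, so the lists end at an IDR of 0.01. The deposited ranked lists give the global IDR per peak as −log10, which was scaled in the same way to tell passing from other candidates. The deposited summit offset gave each peak's position. Of the whole-series lists, the conservative thresholded list (5302 peaks) served as an alternative. The other 3 thresholded and 4 ranked lists of the whole series were not used further, since which replicates they compare is not given in the sources used here.

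Peaks were called per replicate, so replicates could be compared as lists. The median peak width was 340, 340 and 350 bp. Replicates 1 and 2 had 79 intervals with the same start and end, replicates 1 and 3 had 1, and replicates 2 and 3 had 0, so no list repeated another. Only chromosome arms 2L, 2R, 3L, 3R, 4, X and Y entered the analysis, which left out 12, 0 and 1 thresholded peaks. Gene models were the protein-coding genes of Ensembl release 115 for BDGP release 6, whose arm lengths equal those of dm6, and the sequence was the matching NCBI assembly. The 5 list members with older symbols were matched through the synonyms of a gene table.

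Summits of the 3 lists were joined by single linkage at 150 bp, and a region in at least 2 lists was a core region, placed at the summit with the highest within-list percentile of signal. Chance overlap came from 1000 random placements within the chromosome and, as an alternative, from 1000 draws out of each ranked list. Promoters ran from 1000 bp upstream to 200 bp downstream of a protein-coding transcription start site and took precedence over 5′ UTR, coding exon, 3′ UTR, intron and intergenic sequence, in that order. Shares carry 95% Wilson or exact binomial intervals and densities exact Poisson intervals, all for counting error only. Motif presence on either strand was compared between the 100 bp at the summit and 2 windows 500 bp away by an exact conditional test, one-sided for more at the summit, with Benjamini-Hochberg adjustment over the 10 named motifs other than ACGTG. As another background each summit window was shuffled 20 times with its dinucleotides kept, and 20 sets of genome windows away from core regions were matched to 3456 of them on arm and on GC at the summit and in the flanks. Passing and other candidates were compared by a two-sided Fisher's exact test in each replicate, adjusted over the 3 replicates. A gene counted as having a core region if a summit lay in its body or 2 kb upstream. Each of 19 gene lists was compared with 10000 draws of genes matched in 20 bins of length, by a two-sided permutation test with Benjamini-Hochberg adjustment over the lists. Tests over regions or genes describe these 3 lists, and the spread between replicates is given beside them as SD.

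The groups, tests, gene lists and the rule for named genes were set before the data were examined. The rule takes the 15 regions in all 3 lists with the highest mean signal percentile and their nearest gene, up to 4 members per list with the strongest core region, and every bHLH-PAS gene. Alternatives were other demands on support (all 3 lists, the conservative list, each replicate left out, the peaks above the median signal of each list), other definitions of shared (1 bp of interval overlap, summits within 50 bp), promoters from 500 bp upstream to 100 bp downstream and from 2000 to 500 bp, windows of 200 bp, flanks at 1000 bp, other gene territories (start sites within 1 kb, the body with 10 kb on either side) and other matching (length and arm, none). Lists made of all ranked peaks past the threshold, and shuffles for the 10 other motifs, were added after seeing the data.

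The functions were tested on simulated data. Of 2000 summits planted in 3 lists of 3000, 1991 were recovered in all 3. Of 200 planted gene lists of 60 members, 99.5% were called, and of 500 lists drawn at random 3.2% were. Only 1 size of planted effect was simulated, so 99.5% holds for that size alone. Regions otherwise depended on gene length alone, which the matching takes up, so 3.2% does not cover other differences between genes. Smaller lists were not simulated, so the share called does not carry over to them. Of 200 sets of 600 windows with the centre picked at random, 4.5% were called by the motif test. Summit and flank windows were interchangeable in these sets, as the test assumes. The 4.5% therefore does not cover the difference in GC between real summits and flanks. Of 2000 windows, 300 were given ACGTG, which added 268 windows with the motif. The tests were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, with random draws from the seed 20240601, and plots were drawn with matplotlib 3.10.9.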

Results

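Chromatin immunoprecipitation sequencing was performed with an anti-GFP antibody on whole Drosophila melanogaster embryos, collected 0 to 24 h after laying, that carried a GFP-tagged copy of tango (tgo). Tango is the fly homologue of ARNT, a transcription factor of the bHLH-PAS family that binds DNA as a pair with partners such as Single-minded, Trachealess, Spineless and Similar. The series held 1 group of 3 biological replicates and no untagged or treated arm. The questions it can answer are where anti-GFP peaks were called, how far the replicates shared those places, and which genes and sequences lay there. Peaks that are not specific to Tango could not be told apart. The thresholded lists held 3617 peaks in replicate 1, 4759 in replicate 2 and 3027 in replicate 3, or 3801 ± 881 (SD, n = 3). The longer ranked lists from which such peaks are drawn held 35134, 75958 and 33491 candidates. Read depth was not given in the sources used here, so the precision behind each peak is unknown, and intervals below cover counting error only. All positions are on dm6.

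The 3 replicates marked largely the same places. Summits no more than 150 bp apart were joined into 5569 regions, of which 3463 (62.2%) were present in at least 2 lists and are called core regions here, and 2270 were present in all 3. Random placement of the same number of summits per chromosome gave 94.9 ± 9.29 core regions (SD over 1000 placements), and drawing each list at random from its own ranked candidates gave 344 ± 16.5. The observed number was 36.5 times the first and 10.1 times the second, with a permutation p of 0.000999 for both, the smallest that 1000 placements can give. Replicate 2, with the longest list, held 1339 of the 2106 regions seen in a single list.

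Taken list by list, 85.4% of the replicate 1 peaks (95% Wilson interval 84.2 to 86.5%) and 85.4% of the replicate 3 peaks (84.1 to 86.6%) had a replicate 2 summit within 150 bp. The lowest share was that of replicate 2 peaks found in replicate 3, at 54.5% (53.1 to 55.9%). The mean of the 6 directed shares was 72.5% ± 12.6 (SD over the 6 shares, which come from 3 replicates and are not independent), against 3.25% when lists were drawn from the ranked candidates. Regions shared by 2 lists also kept much of their order by the authors' signal: Spearman's rho across regions was 0.865 for replicates 1 and 2 over 3070 regions, 0.781 for replicates 1 and 3 over 2365, and 0.769 for replicates 2 and 3 over 2568. Regions are not independent replicates, so no p is given for these.

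**Figure D1:**
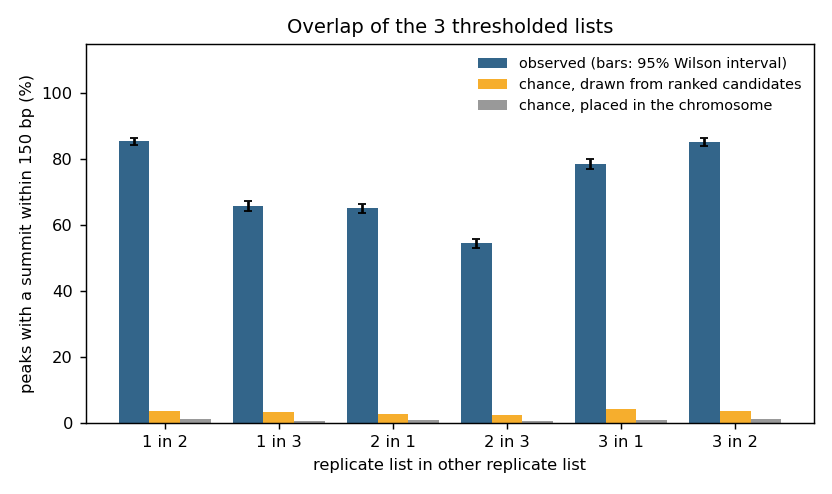
Share of the peaks of each thresholded list (y axis, percent) with a summit of another list within 150 bp, for the 6 directed pairs of replicates (x axis), beside the mean share under both kinds of random draw. Observed shares lie between 54.5% and 85.4%, while no chance share is above 4.06%.

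Most of the strongest shared regions lay in promoters. Among core regions, which leave out the peaks missing from the thresholded lists, those present in all 3 lists were ranked by mean percentile of the authors' signal within each list, and the region at the top was on X from 2703701 to 2704061, with its summit at -25 bp from a start site of Ugalt, which encodes a Golgi UDP-galactose transporter (negative distances are upstream; percentile 99.99 ± 0.016, SD, n = 3). Next came regions at CG14100 (3L, 19590443 to 19590799, summit at -88 bp) and mRpL41, a mitochondrial ribosomal protein gene (2R, 15217575 to 15217904, summit at -131 bp). The remaining regions of the top 15 had CG11050, CG7601, ph-p, CenG1A, Tcs5, Art3, PNPase, CG13323, Chro, CG5611, Fkbp14 and CG18549 as nearest genes. Among these, ph-p encodes the Polycomb group protein Polyhomeotic (X, 2137171 to 2137532), and Chro the chromosomal protein Chromator (3L, 22878736 to 22879061). Of the 15 regions, 13 lay in promoters, with exceptions in an intron of CG11050 (2L, 6612500 to 6612892) and in intergenic sequence 11911 bp downstream of a start site of CG13323 (2R, 13035178 to 13035488). In 9 of the 15 the summit fell between 150 and 50 bp upstream of a start site.

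Core regions as a whole gathered at promoters. Of 3463 core regions, 1660 (47.9%, exact 95% interval 46.3 to 49.6%) had their summit from 1000 bp upstream to 200 bp downstream of a protein-coding start site, 3.64 times the 13.2% found in 1000 random placements (permutation p = 0.000999, one-sided, the smallest possible). The 3 replicate lists gave 47.7% ± 1.79 (SD, n = 3). Within promoters the median summit lay at -142 bp from the nearest start site, with quartiles at -269 and -84 bp over the 1623 regions whose nearest start site was that of the promoter, and the bin from -200 to -50 bp held 791 core regions, 12.9 times its random share. Introns held 1237 core regions (35.7%), close to the random 38.8%, and intergenic sequence held 509 (14.7% against 28.6%). Exons were nearly empty: 10 core regions (0.289%) had their summit in coding exons outside promoters, where random placement put 14.05%, and 29 lay in 3′ UTRs and 18 in 5′ UTRs.

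**Figure D2:**
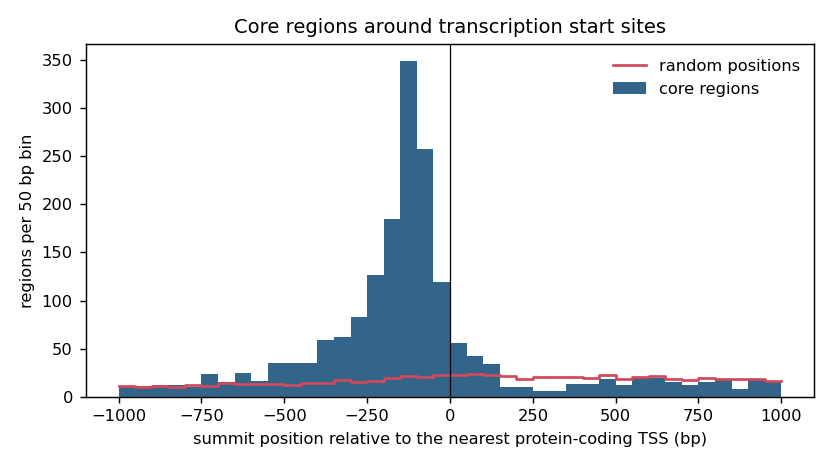
Number of core regions per 50 bp bin (y axis) by summit position relative to the nearest protein-coding transcription start site (x axis, bp; negative values are upstream). Blue bars are core regions and the red line random positions with the same number per chromosome arm; the highest bin, from 150 to 100 bp upstream, holds 349 core regions against 21.4 at random.

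Core regions were spread over all large chromosome arms. X carried 28.8 core regions per Mb (exact Poisson 95% interval 26.7 to 31.1), 3L 26.9, 2L 26.9, 3R 24.5 and 2R 23.9 per Mb. The density on X was 1.13 times that of the autosome arms 2L, 2R, 3L and 3R together, and 1.11 ± 0.053 in the replicate lists (SD, n = 3). The small chromosome 4 held 7 core regions, or 5.19 per Mb (2.09 to 10.7), and the Y held 0, which allows up to 1.01 per Mb.

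The DNA under the summits was rich in A and T, and held the sequences known for Tango pairs less often than the DNA beside it. Mean GC content in the 100 bp centred on the summit was 31.1% in core regions and 43.6% in windows 500 bp to either side, and in the replicate lists 31.9% ± 0.943 against 43.5% ± 0.338 (SD, n = 3). The core ACGTG, bound by Tango with Single-minded, Trachealess or Similar, occurred in 191 of 3463 summit windows (5.52%, Wilson interval 4.80 to 6.33%) and in 9.46% of flanking windows, a ratio of 0.583. The replicate lists gave a ratio of 0.574 ± 0.0792 (SD, n = 3), and the exact one-sided test for more ACGTG at the summit gave p = 1.0. GCGTG, bound by Tango with Spineless, occurred in 5.40% of summit windows and 13.8% of flanks, a ratio of 0.390. Against other backgrounds the deficit was smaller or absent: ACGTG stood at 0.829 times its count in shuffled summit windows that kept every dinucleotide and at 1.04 times its share in genome windows of the same GC content (5.53% against 5.33%), and GCGTG at 0.904 times its shuffled count, inside the range of the shuffles. Across 5 groups of core regions from strongest to weakest, ACGTG was found in 6.35%, 5.63%, 4.62%, 5.92% and 5.06% of summit windows. GCGTG was found in 3.17%, 4.62%, 5.34%, 5.92% and 7.95%. Mean GC at the summit in the same groups was 28.6%, 30.4%, 31.2%, 31.7% and 33.4%. The GCGTG share thus rose together with GC, while the ACGTG share was highest in the group with the lowest GC. The groups also differed in promoter share, which was 63.9% in the strongest and fell from each group to the next. No test was run on these shares.

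**Figure D3:**
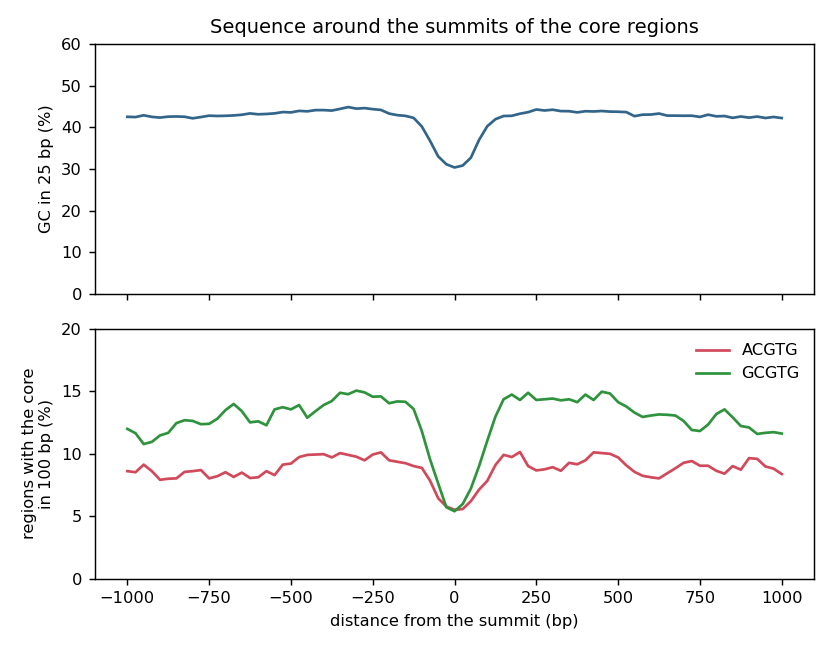
Upper panel: GC content in 25 bp windows (y axis, percent) by distance from the summit (x axis, bp), averaged over the core regions. Lower panel: share of core regions with ACGTG (red) or GCGTG (green) in a 100 bp window (y axis, percent); both fall at the summit, to 5.52% and 5.40%, together with GC, which falls to 30.4%.

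Of the other 10 named sequences, 2 were more frequent at summits than in flanks by the exact one-sided test with Benjamini-Hochberg adjustment. TATCGA, part of the element bound by DREF and BEAF-32 at housekeeping promoters, occurred in 5.02% of summit windows and 3.54% of flanks (ratio 1.42, adjusted exact p = 0.00107; 1.503 ± 0.166 in the replicate lists, SD, n = 3). GATAA, the core bound by GATA factors, occurred in 24.3% and 17.8% (ratio 1.36, adjusted exact p = 6.93e-14). The call for TATCGA was lost without replicate 1 (ratio 1.28, adjusted exact p = 0.0843) and among regions present in all 3 lists (1.34, 0.0563). Against shuffled summit windows that kept every dinucleotide, TATCGA stayed above the shuffled mean (1.56 times, 174 windows against 112), while GATAA fell below it (0.858 times). The E-box forms CACGTG (ratio 0.515), CAGCTG (0.484) and CANNTG (0.812) had an adjusted exact p of 1.0, as did GCGTG. So did TACGTG (0.593), which contains ACGTG, and RCGTG (0.469), which takes in both ACGTG and GCGTG. The same held for the GAGA-factor repeat GAGAG (0.531) and the Zelda-type CAGGTA (0.795). TACGTG (54 windows against 55 to 82 in shuffles) and RCGTG (359 against 382 to 451) also lay below every shuffled set. Shuffling moved CAGCTG, CANNTG and GAGAG from below to above their background, at 2.14, 1.19 and 1.26 times the shuffled count. Of 512 5-mers, 138 were more frequent at summits than in flanks at an adjusted p under 0.05, and 96 of these held at most 1 G or C. TATAA led this ranking with a ratio of 2.37, and ACGTG stood at place 341. Against shuffled windows TATAA was not in excess, at 0.944 times its shuffled count. The 5-mer with the largest excess over shuffles was CACTG, at 1.89 times.

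Peaks past the authors' threshold carried ACGTG less often than candidates that did not pass. In replicate 1 the share was 5.21% of 3682 passing and 8.92% of 30972 other candidates, in replicate 2 it was 6.15% and 9.09%, and in replicate 3 it was 4.98% and 9.44%. The log2 odds ratio was -0.81 ± 0.19 (SD, n = 3), with Fisher's exact adjusted p between 3.53e-18 and 3.37e-13 across the 3 lists. The GC content differed too: candidates that did not pass averaged 45.7% ± 0.273 at their summits (SD, n = 3). With GCGTG in place of ACGTG the log2 odds ratio was -1.41 ± 0.20 (SD, n = 3).

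Genes of the ribosome stood out among the gene lists fixed beforehand. Of 13968 protein-coding genes, 3224 (23.1%) had a core region in the gene body or the 2 kb upstream. Of 92 ribosomal protein genes, 50 (54.3%) did, against 14.7 in draws of genes of matched length (95% of draws 8 to 22), a 3.41-fold excess (permutation p = 0.0002, two-sided, the smallest that 10000 draws can give; Benjamini-Hochberg adjusted p over the 19 lists = 0.0019). The replicate lists gave 54.7% ± 8.302 of members (SD, n = 3). In 49 of the 50 genes the strongest region lay in a promoter, and in 41 it lay no more than 300 bp upstream of the gene's own start site. The highest ranked members were RpL34b (3R, 9401237 to 9401548, summit at -134 bp, signal percentile 93.0 ± 1.53, SD, n = 3), RpS27 (3R, 25247409 to 25247637, 92.1 ± 1.501), RpL32 (3R, 30046240 to 30046460, 89.4 ± 1.07) and RpL7 (2L, 10200934 to 10201130, 85.2 ± 6.64). The proteasome list, taken by symbol prefix alone, did not share this: 6 of 48 members had a core region against 7.93 in matched draws (adjusted permutation p = 0.883). The 6 included Rpn3, Prosbeta6, Prosbeta2 and Rpn11. Whether all 48 genes are used in all cells was not checked. The list turned to 1.17 times its matched genes with the authors' conservative list. The ribosomal protein excess was smaller with 10 kb on either side of each gene, at 1.56-fold.

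Odorant and gustatory receptor genes, expressed in sensory neurons of later stages, lay at the other end. Only 3 of 111 (2.70%) had a core region, namely Or88a, Gr97a and Gr32a, against 20.4 in matched draws (13 to 28; permutation p = 0.0002; adjusted p = 0.0019), and the replicate lists gave 3.00% ± 1.38 (SD, n = 3). With 10 kb on either side of each gene the ratio to matched genes was 0.508 in place of 0.147. The eggshell list, of genes transcribed in the ovary, had 0 of 16 against 2.18, which did not pass the test (adjusted permutation p = 0.454).

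**Figure D4:**
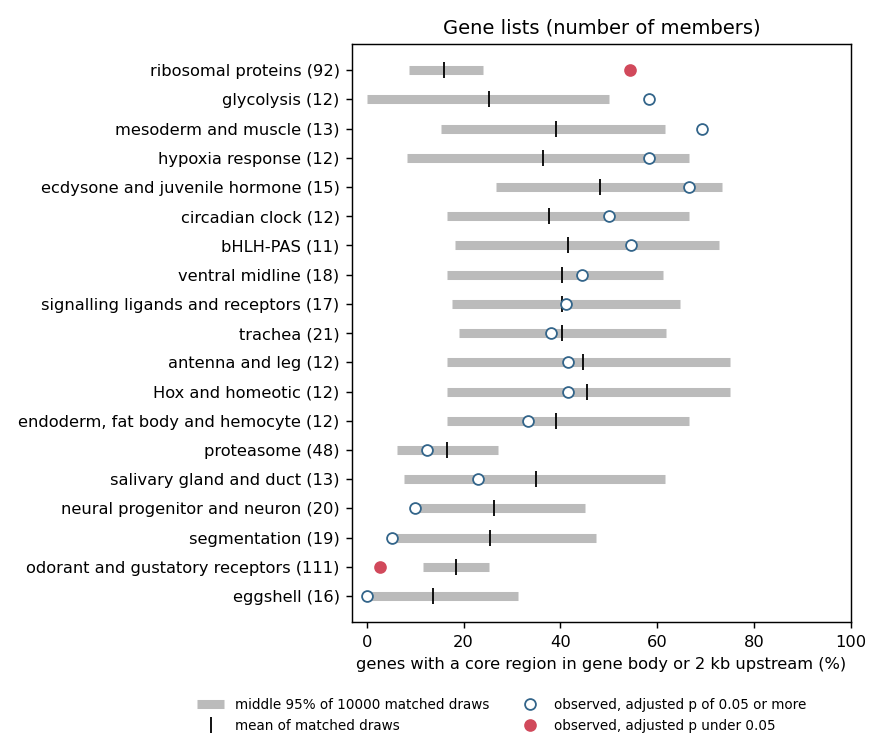
Share of each list's members with a core region in the gene body or 2 kb upstream (x axis, percent) for the 19 gene lists (y axis, number of members in parentheses). Circles are observed shares, grey bars the middle 95% of 10000 matched draws and ticks their mean; ribosomal proteins at 54.3% and odorant and gustatory receptors at 2.70% (filled) are the lists past an adjusted p of 0.05.

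Tango's own family and the tissues its partners pattern were marked about as often as genes of their length. Of 11 bHLH-PAS genes 6 had a core region, against 4.56 in matched draws (adjusted permutation p = 0.867). These were gce, a juvenile hormone receptor (X, 15298317 to 15298649, promoter, percentile 95.5 ± 2.60, SD, n = 3), sima, the fly HIF-alpha (3R, 30061215 to 30061404, intron, 81.4 ± 7.14), the coactivator gene tai (2L, 9166588 to 9166735, promoter, 76.4 ± 7.77), sim (3R, 13068067 to 13068406, intron, 40.2 ± 19.4, present in 2 lists), trh (3L, 377522 to 377861, promoter, 38.8 ± 18.1) and dysf (3R, 26098922 to 26099261, promoter, 33.3 ± 15.2). No core region lay at tgo itself (3R, 9016773 to 9020022) or at ss, cyc, Clk and Met. The ventral midline list, which Single-minded patterns, had 8 of 18 members with a core region against 7.28 (adjusted permutation p = 1.0), led by aos, S, spi and sli. The trachea list, which Trachealess patterns, had 8 of 21 against 8.45 (adjusted permutation p = 1.0), led by crb, sty, grh and pnt. The salivary gland and duct list had 3 of 13 against 4.53 (adjusted permutation p = 0.867; pip, CrebA and trh), and the antenna and leg list 5 of 12 against 5.36 (adjusted permutation p = 1.0; hth, bab2, Antp and Lim1). Some of these turned to the other side of the matched mean: the ventral midline with start sites within 1 kb (0.443 times), the trachea among others with regions of all 3 lists (1.24 times), and the salivary gland and duct (1.01) and antenna and leg (1.80) lists without matching on length. With start sites within 1 kb the antenna and leg list fell to 0 times its matched mean (adjusted permutation p = 0.306). The bHLH-PAS list rose to 1.85 times (adjusted permutation p = 0.464).

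Lists tied to oxygen and sugar use lay above their matched means without passing the adjusted threshold. Of 12 glycolysis genes 7 had a core region against 3.04 (permutation p = 0.0280, adjusted p = 0.177), and in 6 of the 7 the strongest one was in a promoter, with Hex-A as the exception. The glycolysis list stood at 2.30 times its matched genes, at 1.43 with 10 kb on either side and at 2.79 with start sites within 1 kb. Gapdh2 (X, 15867820 to 15868129, percentile 97.2 ± 2.16, SD, n = 3), Eno (2L, 1727783 to 1728048, 94.3 ± 1.23), Hex-A (X, 9583782 to 9584081, 90.4 ± 2.72) and Ldh (3L, 6262778 to 6263008, 88.6 ± 2.46), for glycolytic enzymes and lactate dehydrogenase, ranked highest. The hypoxia response list had 7 of 12 against 4.37 (adjusted permutation p = 0.454), led by Ldh, sima, InR and bnl, and the circadian clock list 6 of 12 against 4.52 (adjusted permutation p = 0.867), led by sgg, Pdp1, cwo and dco. The ecdysone and juvenile hormone list had 10 of 15 against 7.24 (adjusted permutation p = 0.473), with Hr3 highest (2R, 10219923 to 10220231, intron, 98.2 ± 0.0718, SD, n = 3), then gce, Hr4 and ftz-f1; this list passed without matching on length (2.90 times, adjusted permutation p = 0.0038).

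Among developmental lists, mesoderm and muscle genes had the larger share and segmentation genes the smaller, and neither passed the adjusted threshold. In mesoderm and muscle 9 of 13 genes had a core region against 5.08 (permutation p = 0.0484, adjusted p = 0.200). The highest was at Mef2, a master regulator of muscle (2R, 9959747 to 9960073, at -1055 bp from its own start site, percentile 98.7 ± 0.166, SD, n = 3), followed by tin, zfh1 and kirre. In segmentation 1 of 19 had one, at bcd (3R, 6759446 to 6759785, promoter), against 4.83 (permutation p = 0.0526, adjusted p = 0.200). The neural progenitor and neuron list had 2 of 20 against 5.25 (adjusted permutation p = 0.412), at elav, a marker of neurons (X, 523341 to 523629, promoter, 96.9 ± 0.835, SD, n = 3), and insc. Hox and homeotic genes had 5 of 12 against 5.47 (adjusted permutation p = 1.0; hth, Abd-B, Antp and Dfd leading), signalling ligands and receptors 7 of 17 against 6.84 (adjusted permutation p = 1.0; N, dpp, fz and tkv), and endoderm, fat body and hemocyte genes 4 of 12 against 4.68 (adjusted permutation p = 1.0; ush, Hnf4, grn and srp). With start sites within 1 kb, the mesoderm and muscle list turned to 0.660 times its matched mean and the signalling list to 0.704. Without matching on length, the Hox and homeotic list turned to 1.81 and the endoderm, fat body and hemocyte list to 1.46, and the mesoderm and muscle list passed at 2.99 (adjusted permutation p = 0.0076). Lists of 11 to 21 genes give wide matched intervals, so moderate differences were not detectable in them.

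The thresholded lists lacked some strong peaks, which limits statements about genes without a core region and the ranking of the strongest regions. In each replicate about 2.1% of the ranked peaks past the threshold on the major arms (77, 104 and 66 peaks) were absent from the thresholded list, for a reason not given in the sources used here. They formed 68 regions present in at least 2 lists, 45 of them on 3R. The strongest lay on 2L from 480923 to 481258, upstream of cbt, with a mean signal of 1472 over the 3 ranked lists, beside 1463, 1751 and 1180 for the Ugalt region in replicates 1, 2 and 3. Others lay at Lk6 (mean signal 911), larp, tara, trx and pont on 3R. Of the 92 ribosomal protein genes, 1 had such a region and no core region.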

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

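The lists made of all ranked peaks past the threshold and the shuffles for motifs other than ACGTG were chosen after seeing the data. No paired analysis was possible because the series holds 1 group. Apart from the values given here, 94 values that answer a comparison and 383 others kept their direction and call or stayed within their spread. The number of core regions moved with the support asked for: 2270 in all 3 lists, 5302 in the authors' conservative list and 1819 among peaks above the median signal of each list, where fewer or pooled peaks enter by construction, and 2363 to 3068 with 1 replicate left out. With 1 replicate left out, rank agreement was that of the 1 pair left, from 0.769 to 0.865. The promoter share lay between 41.8% and 57.1% under every alternative run and above its random share in each. The ACGTG ratio lay from 0.558 in promoter regions to 0.829 against shuffled windows in the alternatives named for it; outside these, 400 bp windows gave 0.970 and GC-matched windows 1.04. Ribosomal protein genes stayed above and odorant and gustatory receptors below their matched genes in all 13 alternatives, with an adjusted permutation p up to 0.0038. Without matching on length, 3 lists lay above other genes in place of 1, since ecdysone and juvenile hormone genes (2.90 times, adjusted permutation p = 0.0038) and mesoderm and muscle genes (2.99 times, 0.0076), many of them long, then passed.

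Of the 10 other motifs, 1 in place of 2 was called in regions of all 3 lists and above the median signal, and 1 to 2 with 1 replicate left out. The call lost was TATCGA, at ratios of 1.34 (adjusted exact p = 0.0563), 1.36 (0.0830) and, without replicate 1, 1.28 (0.0843); the cause was not tested. Against shuffled windows, which remove the difference in composition from the flanks, GATAA turned to 0.858, and CAGCTG (2.14), CANNTG (1.19) and GAGAG (1.26) turned to above 1.

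Some lists that did not pass changed sides of their matched mean, and the cause was not tested. The trachea list went above 1 in all 3 lists (1.24), with summits within 50 bp (1.00), with 1 replicate left out (1.02 to 1.21) and without matching (1.65). Signalling ligands and receptors went below 1 in all 3 lists (0.762), with 1 replicate left out (0.703 to 0.941), above the median signal (0.677) and with start sites within 1 kb (0.704). Start sites within 1 kb also put the ventral midline at 0.443 and mesoderm and muscle at 0.660. Without matching, salivary gland and duct (1.01), antenna and leg (1.80), Hox and homeotic (1.81) and endoderm, fat body and hemocyte (1.46) rose above 1; the last did so with 10 kb on either side (1.05), and the proteasome in the conservative list (1.17). Read depth, which limits how many weak peaks pass, is unknown for these lists.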

Other observations

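The gene groups by symbol, the position between start sites, the proteasome comparison, the GC-matched ACGTG share as a cause of the deficit, the GC-matched windows for strong regions outside promoters, the 8-mers at X start sites and the counts around tgo and on chromosome 4 were tests chosen only after the results were seen. Other groups of genes differed as ribosomal protein genes and receptors did. Among 31 groups of at least 20 genes sharing a symbol prefix, each compared with length-matched genes by the permutation test, mitochondrial ribosomal proteins (mRp) had a core region at 21 of 73 genes against 9.57 (adjusted p = 0.00372) and PIG genes, of GPI anchor synthesis, at 11 of 21 against 4.18 (adjusted p = 0.0117). Below their matched genes lay cytochrome P450 genes (Cyp, 5 of 85 against 18.03, adjusted permutation p = 0.00207), ionotropic receptors (Ir, 1 of 60 against 12.3, 0.00207), cuticle proteins (Cpr, 2 of 70 against 11.4, 0.00620), UDP-glycosyltransferases (Ugt, 1 of 35 against 6.87, 0.0192), pickpocket channels (ppk, 1 of 28 against 6.10, 0.0406) and histone genes (His, 1 gene against 9.90, 0.00517). Histone genes lie in near-identical copies, in which the authors' read mapping can leave peaks uncertain. The other 3 calls were for prefixes that repeat the ribosomal protein, odorant and gustatory receptor lists.

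Promoter regions often lay between genes read in opposite directions. Of 1660 core regions in promoters, 518 (31.2%) had a start site on either side, facing away from each other and no more than 1000 bp apart, while the same distances set at random start sites of the same arm gave 16.5% (Fisher's exact odds ratio 2.29, p = 6.97e-40).

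The low share of ACGTG at summits went with their low GC content: genome windows matched to 3456 core regions on GC at the summit and in the flanks held ACGTG in 5.33% on average over 20 sets, and the core regions in 5.53%, inside the range of the sets (4.83 to 6.22%). By this control the deficit against flanks goes with GC content. The other control left a deficit: ACGTG was at 0.829 times its count in shuffled windows, below all 20 shuffled sets (191 against 207 to 261). The ratio of 1.04 to matched windows argues against an enrichment hidden by GC over the core regions as a whole, beyond what the range of the sets allows. Only 14.3% of the matched windows lay in promoters, against 47.9% of the core regions, so differences in sequence class were not removed. It stays open whether the core lies beside the summit, since 400 bp windows gave a ratio of 0.970 (exact one-sided p = 0.838), or serves in strong regions outside promoters, where 360 regions gave 1.19 times GC-matched windows (5.83% against 4.90% ± 1.10, SD over 200 sets). A ratio to flanks under 1 had been set to exclude both, but flanks are richer in GC, which lowers such ratios (0.568 in those 360 regions) whether or not the core is used.

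Technical explanations were weighed for the gathering of core regions upstream of start sites and at ribosomal protein genes. If recovery of AT-rich DNA alone had placed them, windows of the same GC would lie in promoters as often, but their highest share in 20 sets was 15.2%, against 47.9%. Crowding of genes does not account for the ribosomal protein list, which held 3.28 times as many genes with a core region as genes matched on length and on neighbours within 5 kb (permutation p = 0.0002, the smallest possible). A signal at all constitutively used genes alike would have put the proteasome list above its matched interval, but it lay inside, at 0.756 times its matched genes. That argues against a signal there as strong as at ribosomal protein genes. It cannot decide for constitutively used genes in general, because the list was taken by symbol prefix and changed sides with the conservative list. Mitochondrial ribosomal protein and PIG genes lay above their matched genes (2.19 and 2.63 times), and 8 of the 31 symbol groups below. Binding of the antibody or of GFP fusions in general at open promoters stays open and untested, because no list from untagged embryos was analysed here, and the design gives no biological contrast to test.

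Some 8-mers were more frequent at summits than in shuffled windows. The 10 with the largest excess on autosomes included GATGGCGC, in 33 of 2785 autosomal windows against 2.3 in shuffles, AGGTGGCG, CACAGTGG and ATCGATAG, and any of the 10 occurred in 5.57% of core regions, 2.79% of their flanks and 0.758% of shuffled windows. Chance among many 8-mers is argued against by X, which was not used to pick them, where their median ratio to shuffles was 6.24 over 678 regions, above all 1000 random sets of 8-mers as frequent (highest 1.71). Several of the 10 overlap in sequence, as GATGGCGC and AGATGGCG do, while each random 8-mer was drawn separately. The margin is therefore not that of 10 separate sequences. The excess over flanks was smaller there, at 5.31% against 3.69% of windows. Sequence common to promoters stays open, since promoter core regions on X held the 8-mers in 6.76% of 281 windows and X start sites without a core region in 4.32% of 2757 (Fisher's exact odds ratio 1.61, two-sided p = 0.0700), and no biological explanation was tested.

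The ranked lists held more candidates around tgo, the tagged gene, than in the median bin of 3R, by different margins. The 100 kb centred on it held 38, 122 and 65 candidates in replicates 1, 2 and 3, which is 1.27, 1.94 and 2.32 times the median of 320 such bins and stands at percentiles 90.0 and 99.1 in replicates 1 and 2 and at the top in replicate 3. Some of the regions past the threshold but absent from the thresholded lists lay in these 100 kb. They included one at Kdm2 (3R, 9057387 to 9057689, mean signal 328) and one at Mst85C (3R, 9048165 to 9048504, 80.5). The labels name tgo as the target of the insertion, and the position of the insertion is not given in the sources used here. Chromosome 4 held fewer candidates per Mb than the other arms in each replicate: 22.3 against 254 in replicate 1, 330 against 554 in replicate 2 and 40.8 against 243 in replicate 3.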
